A study of Homo sapiens with 2 samples.

How the data were processed

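RNA sequencing had been done on neural progenitor cells made from H1, an established human embryonic stem cell line, under 2 inhibitor regimes. Per the labels' protocols, RNA was taken up in Trizol and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. One library came from cells made by dual SMAD inhibition (the dual library) and 1 from cells made by combined inhibition of TGF-beta, BMP and GSK3 signalling (the triple library). Each regime had 1 library, so no spread between replicates could be estimated, and no test, standard error or p-value was computed.

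The deposited values are TPM, a transcript abundance corrected for transcript length and scaled to the same total in each library. Bowtie, RSEM and the builds hg19 and mm10 are named in the submitters' processing notes, with no versions and no statement of which step used which. The annotation and the use of strand are not given in the sources used here. The files list 56266 Ensembl genes with TPM rounded to 2 decimals, and these sum to 998943.4 in the dual library and 999020.5 in the triple library. TPM keeps no record of sequencing depth, so the depth of both libraries is unknown, and no counting interval or detection limit could be given.

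The design fixed before the data were examined was written for read counts. Because the files hold TPM, its fallback for such values was used: the difference in log2(TPM + 1), triple minus dual. The pseudocount of 1 TPM understates the difference of genes with low values. A gene counted as measured with at least 1 TPM in either library, and as higher or lower in the triple library with a difference of at least 2-fold on this scale. Genes at exactly 0 in a library are described as listed at 0, with no fold, because TPM without depth gives no limit for a 0.

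Also fixed before the data were examined were 33 gene lists from textbook knowledge (cell types, brain regions, signalling pathways and cell states). For each, the median difference over measured members was placed among the medians of 10000 random lists of the same size, drawn from measured genes in the same of 20 classes of mean expression. A list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. Percentiles describe these 2 libraries and are no test of the regimes. The random lists treat genes as independent, which members of a gene cluster or pathway are not, and several lists share members. The symbols PECAM1 and SC5D found no match and were not used here. Where a symbol stood on more than 1 Ensembl gene, the gene with the highest summed TPM was taken.

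The rule for named genes took 16 genes whatever their values, up to 4 members per list with the largest absolute difference among those at least 2-fold different (the most abundant member where none was), and the 12 genes with the largest difference in each direction among genes with at least 10 TPM. Single values of 2 genes that the rule takes are not reported here. XIST and Y-linked genes were left out of the table of genes and of the plots. Gene types came from GENCODE release 29 by Ensembl identifier, which matched 94.3% of measured genes. That annotation is on another build than the one in the notes, so no coordinates are printed.

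Another 6 lists were made after the values had been seen (retinoid binding and response, retinoid response, immediate early, WNT feedback, MHC class I and imprinted genes). The retinoid response list is a shorter version of the first, drawn up after the longer one had been run, and all 6 are reported in the closing section. Alternatives were other scalings, pseudocounts of 0.1 and 5 TPM, no minimum or a minimum of 5 TPM, a 4-fold size rule, the mean in place of the median, protein-coding genes alone, protein-coding random lists, and TPM rescaled without mitochondrial, ribosomal protein and ribosomal RNA genes. TMM scaling, intervals from counts and additions to counts were planned and could not be run on TPM.

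The procedure was tested on simulated data, with noise of 0.3 (SD, log2 scale) per library over 18442 genes of which 200 were changed. The changed genes were drawn only from those with a mean of at least 5 TPM over both libraries. Recovery at lower levels was therefore not simulated. The 2-fold rule recovered 92.6% of 68 genes simulated at a 2.83-fold change, 93.7% of 63 at 4-fold and 100.0% of 69 at 8-fold, and took up 0.87% of 18242 unchanged genes. Of 300 unchanged lists of 20 genes, 6.7% stood apart. The noise between real cultures of one regime is not known from these files, so these shares do not carry over to the real counts. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.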

Results

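The transcriptomes of neural progenitors derived from H1 human embryonic stem cells were compared between dual SMAD inhibition, which blocks the TGF-beta/activin and BMP branches of SMAD signalling, and a triple regime that also inhibits GSK3, a kinase whose inhibition stabilises beta-catenin and activates WNT signalling. The series title describes the cells of the triple regime as PAX6-negative and self-renewing, so the comparison asks how their neural identity, regional identity and cell cycle genes differ from those of cells made by dual inhibition. There was 1 library per regime and no replicate, so each difference below describes these 2 libraries and has no replicate check. Values are TPM, and log2 differences are on the log2(TPM + 1) scale, triple minus dual.

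Both libraries expressed neural progenitor genes such as SOX1 and NES, and they differed most in genes of position along the head-to-tail axis. Forebrain transcription factors such as OTX2 and EMX2 were abundant in the dual library and at 0.34 TPM or listed at 0 in the triple library, whereas HOX genes, which pattern the hindbrain and spinal cord, were near 0 in the dual library and reached 252 TPM (HOXB9) in the triple library. PAX6 was lower in the triple library but still at 39.1 TPM. Of 18442 measured genes, 2552 were at least 2-fold higher and 2470 at least 2-fold lower in the triple library. Among the 13551 protein-coding genes, these numbers were 1253 and 1137. The share of protein-coding genes past 2-fold was 62.1% at mean levels under 1 TPM, 33.8% at mean levels of 1 to 5 TPM and 3.1% above 100 TPM. Mean levels here are averages of log2(TPM + 1) returned to TPM. A measured gene under 1 TPM on that mean reaches 1 TPM in only 1 library, so the filter itself favours a difference there. Among processed pseudogenes of any level the share was 67.0%. Of the 33 gene lists, 12 stood above and 6 below the random lists. Over both sides together, 1.7 lists would stand outside by chance if the genes within a list varied independently, which clusters and pathways do not.

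**Figure D1:**
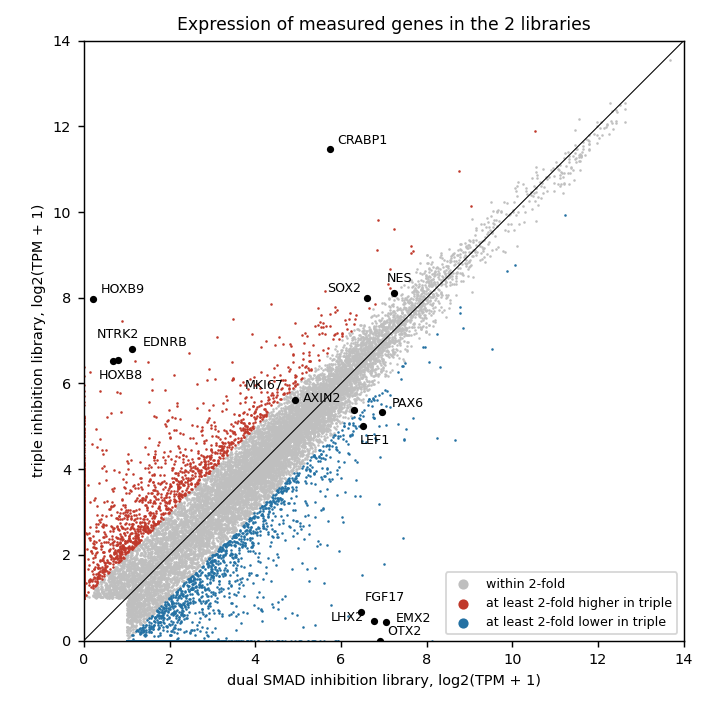
Each point is a measured gene, with its level in the dual library on the horizontal axis and in the triple library on the vertical axis, both as log2(TPM + 1). Red and blue points are at least 2-fold higher or lower in the triple library, the line marks equal levels, and OTX2 lies on the lower edge while HOXB9 lies near the left edge.

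PAX6 (ENSG00000007372), a transcription factor of neuroectoderm and of forebrain and spinal cord progenitors, stood at 124 TPM in the dual library and 39.1 TPM in the triple library, a log2 difference of -1.64. SOX2, a transcription factor of neural and pluripotent stem cells, went the other way, from 96.4 to 256 TPM (1.40). The intermediate filament gene NES was at 150 and 276 TPM (0.87) and SOX1 at 17.4 and 19.6 TPM (0.17). Of 21 measured pan-neural progenitor genes, 6 were higher, 3 were lower and 12 were within 2-fold, and the list median of 0.31 lay at percentile 98.73 of the random lists. The largest differences were in CRB1, an apical polarity gene (0.39 to 15.8 TPM), the neural transcription factors POU3F2 (6.53 to 80.1 TPM) and SOX21 (2.14 to 20.5 TPM), and the adhesion molecule NCAM1 (13.97 to 50.04 TPM). Genes of the neural rosette stage did not stand apart: 2 of 11 were higher, 1 was lower and the median of 0.44 lay at percentile 97.29. The mean of 0.22 lay at percentile 79.15. Against random lists of protein-coding genes, with 10 members kept, the median was 0.51 and stood above (percentile 98.43). Within that list ZBTB16 (3.82 to 12.2 TPM) and LIX1 (5.19 to 11.9 TPM) were higher and MECOM (21.4 to 2.40 TPM) was lower.

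Forebrain genes were lower in the triple library. Of 23 measured members 18 were lower, 2 were higher (NR2F1 and NR2F2) and 3 were within 2-fold, with a median of -2.65 at percentile 0.0. OTX2 (ENSG00000165588), which marks forebrain and midbrain, went from 119 TPM to a listed 0. EMX2 went from 132 to 0.34 TPM, LHX2 from 109 to 0.37 TPM and FEZF2 from 71.1 to 0.49 TPM. Eye field genes, 6 of whose members are also on the forebrain list, were lower in 9 of 10 cases, with a median of -2.19 at percentile 0.0. SIX3 (13.2 TPM) and RAX (6.39 TPM) were present in the dual library and listed at 0 in the triple library. In the list of choroid plexus and cortical hem genes, 2 of 9 were higher and 2 were lower. Its median of 0.51 lay at percentile 93.6, while its mean was -0.44, with OTX2 and WNT8B both listed at 0 in the triple library. Epithelial genes were lower alongside the forebrain genes. Of 13 measured genes of non-neural ectoderm and placode 7 were lower and 1 was higher, with a median of -1.16 at percentile 0.06 (-0.60 at percentile 0.54 over members above 0 TPM), including KRT19 (14.7 to 0.78 TPM), KRT5 (3.32 TPM to a listed 0) and EPCAM (8.26 to 1.22 TPM). TFAP2A, which is also a neural crest gene, was the higher one (0.98 to 9.92 TPM).

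Midbrain and isthmus genes split. The isthmic growth factor FGF17 (87.2 to 0.59 TPM) and the midbrain factor EN1 (10.8 to 0.19 TPM) were lower, whereas IRX3 (4.52 to 104 TPM) and IRX5 (listed at 0, then 32.2 TPM), which are also expressed along the caudal neural tube, were higher. EN2 was at 17.7 and 9.89 TPM (-0.78). Altogether 5 of 18 were higher and 7 were lower, and the median of -0.41 lay at percentile 3.15. The list depended on the filter: it was -0.96 and stood below over members with at least 5 TPM, and -0.20 at percentile 14.31 over members above 0 TPM. Against random lists of protein-coding genes it stood below at -0.41, and its mean of -0.41 lay at percentile 6.21.

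Hindbrain genes and HOX genes were higher in the triple library. Of 20 measured hindbrain genes 17 were higher and none was lower, with a median of 2.68 at percentile 100. GBX2, a factor of the anterior hindbrain, was at 13.8 and 37.3 TPM (1.37). HOXB3 went from 0.11 to 76.7 TPM, and HOXB2 (82.1 TPM), HOXD4 (51.5 TPM) and HOXC4 (37.0 TPM) were listed at 0 in the dual library. Of the HOX genes of paralog groups 5 to 13, 15 were measured and 14 were higher, with a median of 4.11 at percentile 100. HOXB9 (ENSG00000170689) had the highest level, 252 TPM against 0.16 TPM, with HOXB8 at 90.5 against 0.60 TPM, and HOXC6 (44.0 TPM) and HOXB7 (36.2 TPM) were listed at 0 in the dual library. Over the 4 clusters, each of the 27 HOX genes of groups 1 to 9 had at least 1 TPM in the triple library (1.16 to 252 TPM, median 20.7 TPM), and none reached 1 TPM in the dual library. Of the 12 HOX genes of groups 10 to 13, none reached 1 TPM in either library.

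**Figure D2:**
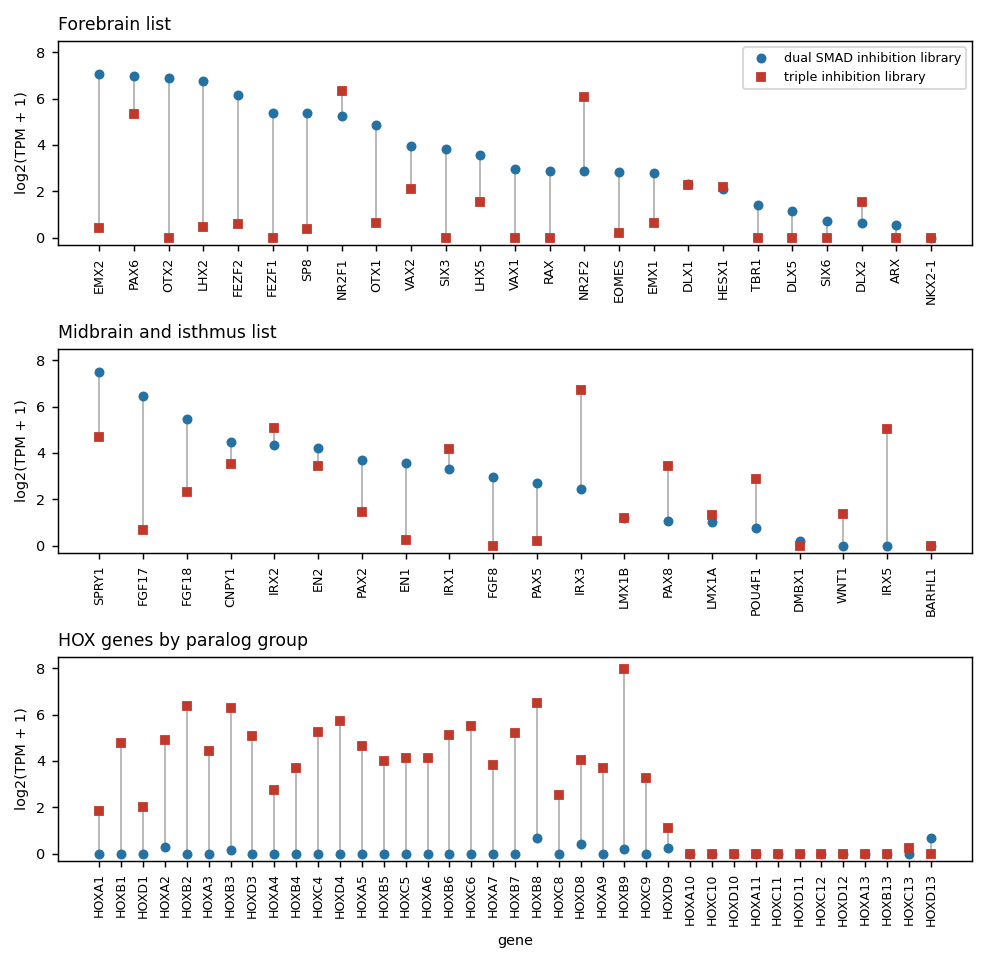
Levels of genes of the forebrain list, all but 1 of its members (top), midbrain and isthmus genes (middle) and HOX genes ordered by paralog group (bottom), as log2(TPM + 1), with circles for the dual library, squares for the triple library and a line joining the 2 values of a gene. Most forebrain genes were near 0 in the triple library, and the 27 HOX genes of groups 1 to 9 were above 1 TPM only in the triple library.

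Along the back-to-belly axis the list medians did not stand apart. Of 18 dorsal neural tube genes 5 were higher and 2 were lower, with a median of 0.34 at percentile 97.12. That list stood above with the mean (0.58, percentile 99.28) and with a pseudocount of 0.1 (0.44, percentile 99.05), and was at 0.16 and percentile 75.58 over members with at least 5 TPM. The roof plate and dorsal progenitor genes WNT3A (0.30 to 25.2 TPM), OLIG3 (2.23 to 36.4 TPM), GDF7 (0.21 to 5.6 TPM) and MSX1 (6.88 to 31.6 TPM) led it. Ventral genes were sparse, with 8 of 18 measured and 3 higher, 2 lower and a median of 0.76 at percentile 90.99, which was 0.03 at percentile 57.01 over members above 0 TPM. NKX6-1 (0.16 to 3.55 TPM), OLIG1 (0.20 to 2.26 TPM) and OLIG2 (listed at 0, then 2.52 TPM) were higher, and NKX6-2 went from 1.26 TPM to a listed 0.

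Neural crest, neuronal and glial lists stood above the random lists. Of 20 neural crest genes 8 were higher and 3 were lower, with a median of 0.80 at percentile 99.96. The endothelin receptor EDNRB went from 1.19 to 109.9 TPM, NGFR from 2.73 to 17.6 TPM and SOX10, a factor of migrating crest and glia, from 0.16 to 4.40 TPM. The 3 lower crest genes were SOX9 (17.8 to 7.47 TPM), SNAI2 (5.75 to 2.01 TPM) and SOX8 (7.67 to 2.14 TPM). Of 33 neuronal differentiation genes 14 were higher and 4 were lower, with a median of 0.74 at percentile 100. The other 15 were within 2-fold, among them TUBB3 (485 to 503 TPM), MAP2 (67.4 to 92.2 TPM) and DCX (6.99 to 8.91 TPM). The proneural factor NEUROG2 (0.97 to 13.9 TPM) was higher, and the GABA-synthesis genes GAD2 (10.6 to 0.74 TPM) and GAD1 (5.55 TPM to a listed 0) were lower. Of 19 genes of glia and radial glia 9 were higher and 4 were lower, with a median of 0.98 at percentile 99.98, which was 0.63 at percentile 99.79 over members above 0 TPM. Higher members included the neurotrophin receptor NTRK2 (0.74 to 93.1 TPM), PTPRZ1 (21.7 to 84.7 TPM) and S100B (listed at 0, then 7.01 TPM). The 4 lower members were NFIA (10.2 to 2.02 TPM), NFIB (2.11 to 0.37 TPM), SOX9 (17.8 to 7.47 TPM) and ALDH1L1 (1.04 TPM to a listed 0). The list thus did not move as a whole.

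The core pluripotency factors were under 1 TPM, POU5F1 at 0.85 and 0.15 TPM and NANOG listed at 0 in both libraries. Even so, 5 of the 7 measured members of the pluripotency list were higher and none was lower, with a median of 1.45 at percentile 99.99, which was 0.83 at percentile 99.87 over the 12 of 18 members above 0 TPM. They included LIN28A, an RNA-binding protein also present in early neural progenitors (12.1 to 64.7 TPM), DPPA4 (4.82 to 25.6 TPM), SALL4 (12.1 to 34.7 TPM) and GDF3 (0.36 to 5.28 TPM). In the mesoderm and neuromesodermal list, the neuromesodermal genes T, NKX1-2, CDX1, CDX2 and CDX4 were listed at 0 in both libraries, so its median does not cover them. Of its 6 measured genes 4 were lower, with a median of -1.36 at percentile 0.94. These were EOMES (6.16 to 0.14 TPM), which is also on the forebrain list, KDR (3.12 to 0.16 TPM), MEOX1 (6.28 to 1.32 TPM) and FOXC1 (12.3 to 5.28 TPM). That call was lost over members above 0 TPM (-0.64), over members with at least 5 TPM (-1.65) and with a pseudocount of 0.1 (-1.72).

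Endoderm genes were measured in 4 of 14 cases, with 2 higher (APOA2 at 1.29 TPM and AFP at 1.00 TPM, both listed at 0 in the dual library) and a median of 0.95 at percentile 90.41, which passed the high percentile over members above 0 TPM (0.82). Of 18 mesenchyme and smooth muscle genes 5 were higher and 2 were lower, with a median of 0.35 at percentile 96.45. Over members with at least 5 TPM that list stood above (0.52, percentile 99.04). ACTA2 (4.28 to 16.3 TPM), TPM2 (14.7 to 46.8 TPM) and COL3A1 (3.08 to 11.2 TPM) were higher and PRRX1 (13.8 to 4.29 TPM) was lower. Blood, endothelial and immune genes were measured in 5 of 14 cases, 2 higher and 2 lower, with a median of 0.52 at percentile 75. HBE1 (listed at 0, then 3.27 TPM) and TIE1 (0.98 to 5.71 TPM) were higher and VWF (1.51 TPM to a listed 0) was lower.

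WNT target genes were lower in the library labelled as made with a GSK3 inhibitor. Of 21 measured targets 11 were lower, 4 were higher and 6 were within 2-fold, with a median of -1.15 at percentile 0.0. The 4 higher ones were CCND1 (57.3 to 218 TPM), MYC (3.73 to 19.99 TPM), NKD2 (6.03 to 24.2 TPM) and KREMEN1 (3.98 to 11.45 TPM). AXIN2, a feedback inhibitor of the pathway, was at 77.6 and 41.0 TPM (-0.90) and LEF1, a partner of beta-catenin, at 90.6 and 31.4 TPM (-1.50). SP5 (36.5 TPM) and DKK4 (47.4 TPM) in the dual library were listed at 0 in the triple library, DKK1 went from 89.4 to 1.91 TPM and SP8 from 40.9 to 0.29 TPM. WNT ligands and antagonists stood above the random lists, with 5 of 18 higher and 4 lower and a median of 0.54 at percentile 99.61, a call that was lost with the mean in place of the median (0.31). WNT3 (2.12 to 36.8 TPM) and WNT10B (listed at 0, then 10.4 TPM) were higher, and WNT8B went from 40.6 TPM to a listed 0.

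Targets of FGF and ERK signalling were lower in 8 of 19 cases and higher in 3, with a median of -0.70 at percentile 0.0 and a mean of -0.37 at percentile 1.65. The feedback inhibitor SPRY1 (178 to 24.7 TPM) and the transcription factor ETV4 (177 to 25.0 TPM) were lower, whereas the receptors FGFR3 (3.30 to 72.6 TPM) and FGFR2 (5.20 to 62.3 TPM) were higher. The remaining higher member was EGR1 (26.9 to 121 TPM). Targets of the pathways blocked in both regimes did not stand apart. The median of 12 TGF-beta and activin targets was 0.04 at percentile 53.16, with 2 higher (CTGF, 45.1 to 159 TPM, and CYR61, 50.1 to 105 TPM) and 1 lower (INHBA, 1.32 TPM to a listed 0). The median of 16 BMP targets was 0.31 at percentile 93.26, with 4 higher and 2 lower, among them GREM1 (3 to 25.4 TPM), GATA2 (0.69 to 3.12 TPM) and ID4 (23.3 to 57.8 TPM).

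Notch pathway genes went both ways, 7 of 19 higher and 5 lower. The median of -0.02 lay at percentile 34.34, and the mean of 0.13 had the opposite sign. HEY1 (79.9 to 9.29 TPM) and HES1 (139.9 to 43.1 TPM) were lower, and DTX4 (16.6 to 115 TPM) and HES4 (46.8 to 169.7 TPM) were higher. The median of 9 hedgehog pathway genes was -0.01 at percentile 35.98, with GLI1 lower (1.48 to 0.15 TPM) and the other 8 within 2-fold.

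**Figure D3:**
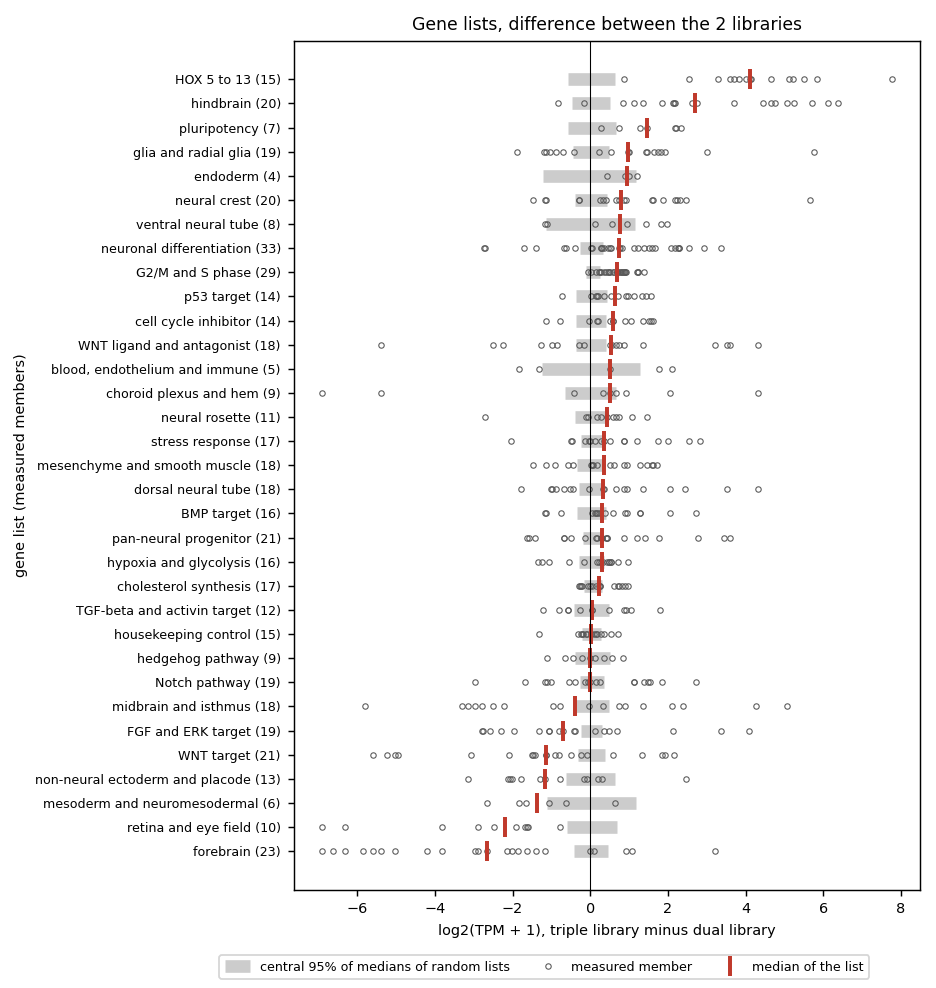
Difference between the 2 libraries in the 33 gene lists, triple minus dual on the log2(TPM + 1) scale, with the number of measured members in parentheses. Circles are members, red ticks are list medians and grey bars span the central 95% of the medians of 10000 random lists matched on expression; the HOX list (4.11) and the forebrain list (-2.65) have the outermost medians.

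Genes of S phase and mitosis were modestly higher in the triple library. Only 4 of 29 passed 2-fold and none was lower, but the median of 0.69 lay at percentile 100. CDK1 (67.8 to 179 TPM), BIRC5 (81.2 to 192 TPM), AURKA (29.4 to 70.1 TPM) and CCNA2 (47.1 to 109.7 TPM) passed it, and the proliferation marker MKI67 was at 29.4 and 48.1 TPM (0.69). Cell cycle inhibitors were higher as well. Of 14, 5 were higher and 1 was lower, with a median of 0.58 at percentile 99.7, including CDKN1B (33.5 to 104 TPM), BTG1 (26.6 to 77.6 TPM), BTG2 (5.42 to 18.1 TPM) and GADD45G (9.61 to 26.4 TPM). Of 14 p53 targets, 3 of them also on the inhibitor list, 4 were higher and none was lower, with a median of 0.62 at percentile 99.71. PHLDA3 (3.06 to 9.87 TPM), the apoptosis gene BBC3 (7.28 to 19.9 TPM) and SESN1 (10.2 to 23.5 TPM) were among them.

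Stress response genes were higher in 5 of 17 cases and lower in 1, with a median of 0.35 at percentile 97.9, a call that was lost over members above 0 TPM (0.31). FOS (48.8 to 287 TPM), FOSB (3.28 to 29.1 TPM) and JUNB (6.86 to 30.4 TPM) were higher and ATF3 (59.4 to 13.7 TPM) was lower. Mitochondrial transcripts made up 5.10% of TPM in the dual library and 4.29% in the triple library, and ribosomal protein genes 22.3% and 19.7%. Of 16 hypoxia and glycolysis genes none was higher and 3 were lower, the glucose transporters SLC2A1 (300.2 to 143 TPM) and SLC2A3 (54.0 to 22.3 TPM) and the gene ANKRD37 (6.79 to 2.08 TPM). The median of that list was 0.29 at percentile 95.23, while its mean was 0.05 at percentile 51.75. All 17 cholesterol synthesis genes were within 2-fold, with a median of 0.23 at percentile 91.19 and FDPS, the most abundant, at 323 and 530.2 TPM. The 15 housekeeping control genes had a median of 0.02 at percentile 44.82, which was -0.01 under median-of-ratios scaling, and a mean of -0.02, and POLR2A, the largest subunit of RNA polymerase II, was the member past 2-fold (64.7 to 25.2 TPM).

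Over all genes with at least 10 TPM, the 12 largest differences in the higher direction were led by HOX genes and also held CRABP1 (ENSG00000166426), a retinoic acid binding protein, at 52.7 and 2827 TPM, and the natriuretic peptide gene NPPC, listed at 0 and then at 71.3 TPM. The antisense genes HOXB-AS3 (0.86 to 175 TPM) and HOTAIRM1 (listed at 0, then 55.8 TPM) lie within HOX clusters, and AL161626.1 (listed at 0, then 61.0 TPM) has no gene type in the annotation used. The 12 largest in the lower direction held forebrain genes together with the pseudogenes RPS2P46 (278 TPM to a listed 0) and SUMO2P1 (59.9 TPM to a listed 0), the antisense genes EMX2OS (60.0 TPM to a listed 0) and FEZF1-AS1 (44.5 TPM to a listed 0), and AL132780.1 (58.4 TPM to a listed 0). Values of pseudogenes share reads with their parent genes, and antisense genes cannot be told from their partners without strand information, so these are uncertain.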

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

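The settings restricted to protein-coding genes, with a pseudocount of 5, with random lists of protein-coding genes, with a pseudocount of 0.1 for lists and named genes, with median-of-ratios scaling for named genes, and rescaled without abundant classes were chosen after seeing the data. No list that stood apart changed direction under a setting that was run, while 6 values of 4 lists that did not stand apart lay on the other side of 0: Notch pathway (0.19 with members of at least 5 TPM, 0.13 with the mean), hedgehog (0.003 with members above 0 TPM), choroid plexus and hem (-0.44 with the mean) and housekeeping (-0.01 with median-of-ratios scaling, -0.02 with the mean). The 2552 higher and 2470 lower genes became 1223 and 1049 with a minimum of 5 TPM, 671 and 538 with a 4-fold rule, 1253 and 1137 among protein-coding genes, and 783 and 596 with a pseudocount of 5, since each of these rules admits fewer genes. They were 3106 and 3006 with a pseudocount of 0.1, and 2884 and 3246 when rescaled without abundant classes, where lower calls outnumbered higher ones, as they also did with median-of-ratios (2458 and 2544) and upper-quartile scaling (2442 and 2562). Removing the minimum altered nothing, because a 2-fold difference on the log2(TPM + 1) scale already needs 1 TPM. The share of higher among all calls was 50.8%, with a range of 47.0% to 56.8% over the settings. No scaling shifted all genes by more than 0.1 on the log2 scale.

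Of 227 list values under other settings, 215 kept their side of the percentiles, 5 no longer stood apart and 7 newly did. With members above 0 TPM, mesoderm (-0.64) and stress response (0.31) no longer stood apart and endoderm (0.82) newly did. With members of at least 5 TPM, mesoderm (-1.65) no longer stood apart, and midbrain and isthmus (-0.96) and mesenchyme (0.52) newly did. With the mean, WNT ligands and antagonists (0.31) were lost and dorsal neural tube (0.58) was gained. With a pseudocount of 0.1, mesoderm (-1.72) was lost and dorsal neural tube (0.44) was gained. Against protein-coding random lists, neural rosette (0.51) and midbrain and isthmus (-0.41) were gained. This setting also leaves out members that the annotation used does not give as protein-coding, which includes identifiers without a match there. These were 1 of 11 in the rosette list and none in the midbrain list. The filters on members change which genes enter; otherwise the cause was not tested. In all, 38 values in 25 lists kept their sign and lay over 1.5 times from the main median, near-zero medians included. For example, with a pseudocount of 0.1 the forebrain list was at -4.71, hindbrain at 5.51 and HOX at 7.26, over members above 0 TPM pluripotency was at 0.83 and non-neural ectoderm at -0.60, and the mean of the FGF and ERK list was -0.37. Among 48 values of the 16 genes named in advance, all kept their side of the 2-fold rule except POU5F1 with a pseudocount of 0.1 (-1.93 against -0.69), which is under 1 TPM in both libraries and so counts as not measured; other named genes were not run under other settings. TMM scaling, additions to counts and the rule on counting intervals were planned and not run, since the files hold TPM. No paired analysis was possible because each regime has 1 library. Depth is unknown, so it cannot be said which of the values near 0 were measurable.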

Other observations

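The tests in this part were chosen only after the values had been seen, and so were the retinoid, MHC class I, immediate early, imprinted and WNT feedback lists, the symbol families and the genes named here that the report does not name; the WNT target, forebrain and HOX lists were fixed before. Genes of retinoic acid handling differed in both directions. RARB, a receptor gene that retinoic acid induces, was at 1.03 and 16.8 TPM in the dual and triple libraries, the degrading enzyme CYP26A1 at 0.63 and 10.8 TPM, and the synthesising enzyme ALDH1A2 was listed at 0 and at 8.52 TPM. The uptake receptor STRA6 (81.2 to 12.5 TPM), RDH10 (110.0 to 25.4 TPM) and ALDH1A1 (20.1 TPM to a listed 0) were lower. Over 15 genes of retinoid binding and response 8 were higher and 3 were lower, with a median of 1.07 at percentile 100.

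Of 8 measured MHC class I genes 3 were higher and none was lower, with a median of 0.75 at percentile 99.64. HLA-B was at 29.3 and 169 TPM and HLA-C at 19.6 and 231 TPM. These genes are near-identical in parts and share reads, so the values of single members are uncertain. Of 17 measured immediate early genes 6 were higher and 2 were lower (ATF3 and IER3, the latter at 86.0 and 9.39 TPM), with a median of 0.72 at percentile 100. Of 18 measured imprinted genes 1 was higher and 2 were lower, and the median of -0.07 at percentile 20.79 did not stand apart, although DLK1 was at 173 and 4.23 TPM. Among 229 families of protein-coding genes with a shared symbol stem, 14 stood above and 14 below random lists. By chance 5.7 on each side would do so if the genes within a family varied independently. Keratins (median -1.66) and collagens (-0.56) were among the lower families, and POU factors (1.31) and mitochondrial ribosomal MRPL proteins (0.31) among the higher.

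PAX6 stayed at 39.1 TPM, 31.5% of its dual level, in cells that the series title calls PAX6-negative. Carry-over of forebrain cells into the triple culture would bring their other abundant transcripts in like share. The 9 other forebrain genes with at least 20 TPM in the dual library had a median of 0.34% of their dual level, and 8 of them lay under 5% (NR2F1 was higher instead), which argues against carry-over. Whether the labels were exchanged cannot be told from these values: the lower WNT targets in the library labelled as GSK3-inhibited (median -1.15) would go with an exchange, whereas its lower forebrain list and higher HOX list would go against one if WNT activation makes neural tissue more caudal, and PAX6 itself was lower (-1.64) in the library whose cells the title calls PAX6-negative, as the labels stand. PAX6 transcription in progenitors of more caudal character is a possible explanation that these bulk values leave open and untested, as is a difference between transcript and protein.

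WNT targets were lower in the library labelled as made with a GSK3 inhibitor, where the pathway would be thought active. The loss of forebrain-restricted targets cannot be told apart from a lower pathway output. Without the member shared with the forebrain list the median was -1.03, still at percentile 0.0. Only 1 of 21 members is shared, however, so the lists cannot decide between these explanations. A subset of 8 feedback genes of that same list, picked after the values were seen and without its members past 2-fold in the higher direction, had 4 lower and none higher and a median of -1.17 at percentile 0.01, which is no separate evidence. Whether the inhibitor was present at harvest is not given in the sources used here and stays open.

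CRABP1 was at 52.7 and 2827 TPM. Reads moved to it from its paralog CRABP2 are argued against, because CRABP2 was higher too (269 to 495 TPM, log2 difference 0.88). A retinoid response is a hypothesis. A list of 7 response genes had a median of 1.13 at percentile 98.75, with 5 higher and STRA6 lower, but it was a shortened form of the 15-gene list, drawn up with the values known, so its outcome decides nothing. A response cannot be told apart here from the caudal identity that the HOX genes show, and medium composition is not given in the sources used here.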
